A study of Danio rerio with 12 samples.

How the data were processed

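The counts table was deposited by the authors as raw whole-number counts per Ensembl gene, 1 column per sample and 32520 genes, and the unit counts comes from the values themselves, which are whole numbers and differ in depth between columns. Per the submitters' processing notes STAR and featureCounts were used on the danRer11 genome build, and the versions, settings and role of each tool are not given in the sources used here. The TPM table was also deposited by the authors, the unit TPM (transcripts scaled to a fixed total) being named in its label and borne out by columns with the same sum. Count divided by TPM was a gene factor times a column factor within 4.4e-08 on the log scale over 4982 genes with counts in all libraries, so the tables hold the same measurement. The deposited values are not pooled, and no mapping was redone here because the reads were not at hand. Duplicate removal, strandedness of the library, the annotation release and the handling of reads shared by paralogs are not given in the sources used here, so levels of paralogs and of genes overlapping on opposite strands carry that uncertainty.

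Gene names came from the gene name table supplied with the task, which gave a symbol to 29201 of 32520 identifiers and none to 3319. A symbol was shared by more than 1 identifier for 6314 genes, and those are printed with their identifier. Names given in the plan were matched by symbol or RefSeq synonym, cldnh being cldn3c, grn2 being grna.2 and spi1b being SPI1 (ENSDARG00000000767). There were 27 gene lists, written from general knowledge before the tables were opened, and 897 of 951 members were found by symbol, synonym or shared symbol of duplicated copies, with at most 4 identifiers per symbol. The lists were leukocyte and macrophage identity, pattern recognition receptors, phagocytosis machinery, MHC class II antigen presentation, dendritic cell genes, tight junction and epithelial adhesion, keratins and epithelial cytoskeleton, epithelial transcription factors, lysosome and cathepsins, vacuolar ATPase, endocytosis of soluble cargo, cytokines and chemokines, interferon-stimulated genes, cell cycle, immediate early and heat shock genes, lipid handling genes of macrophages, iron handling, T cell and NK cell markers, B cell markers, neutrophil and granulocyte markers, enterocyte and goblet cell markers, ionocyte and gill epithelium markers, mitochondrial genome transcripts and cytosolic ribosomal proteins. The remaining lists (erythrocytes and thrombocytes, pancreatic acinar cells, endothelial and stromal cells) had fewer than 5 tested members and were not tested.

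Genes were kept by filterByExpr of edgeR 4.0.16 with its default settings over the 4 groups, which left 10666. Library sizes were adjusted by TMM, dispersions were estimated over all 12 libraries, and a quasi-likelihood F test was made on a model with 1 mean per group and 8 residual degrees of freedom. The 6 contrasts were GFP against DsRedx in gill, the same in intestine, gill against intestine in GFP cells, gill against intestine in DsRedx cells, the mean reporter effect and the difference of the reporter effects. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes of a contrast. The counts of list members called were made on those p-values and once more adjusted over the list alone. Lists were tested with camera of limma 3.58.1 on the same edgeR data and design at its preset correlation of 0.01, and adjusted over the 24 lists of a contrast. Fold changes were the model's own, except where 1 of the groups compared had no count: there the fold is a floor made from 3 counts over the group, and with 1 to 3 counts in a group the ratio of pooled rates is given with an exact 95% Poisson interval. CPM values in the text are edgeR counts per unit of TMM-adjusted library size, on its standard CPM scale, and percentages of a library are of its raw total.

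Named genes were picked by a rule written before the data were opened. For each reporter comparison these were the 8 called genes with the largest rise and the 8 with the largest fall whose 3 library values did not overlap between groups and whose mean was at least 50 CPM in the higher group, clone-named genes excepted, and 6 each for the tissue comparisons and the difference. Up to 4 called members of each list were added, or the 2 of highest CPM where none was called, and mpeg1.1, sox17, cdh1, epcam, cldnh, grn2, csf1ra, csf1rb, marco, spi1b, irf8 and cd4-1 were always looked up. The text gives preference to genes called in all 12 fits that each left out 1 library.

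Alternatives were RLE and upper-quartile scaling, no filter, a stricter filter of 10 CPM in 3 libraries, a robust dispersion, a called gene also over 2-fold, a replicate-number block, the number of detected genes as a covariate, only the 2 groups of a contrast in the fit, DESeq2 1.42.0 and limma-trend on log2 TPM with a pseudocount of 1 or 0.1 and with or without a filter at 1 TPM. For lists, camera with a correlation estimated from the data and fry were run. Each of the 12 libraries was left out in turn. After the results were seen the samples were also split in other balanced ways, and 2 alternatives were added, one without the most abundant gene and one in which a low level common to the libraries of a tissue was removed. For the latter, each library's rate was the median, over genes with at least 3000 counts in the 5 other libraries of its tissue and itself under 0.5% of that sum, of its count in percent of the sum (0.147 to 0.343%). A count of at most 0.5% of the sum was set to 0 and a larger one reduced by the rate times the sum, which took away at most 1.53% of a library's counts.

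The pipeline was tested on simulated data made from the gill libraries with 9893 genes tested. With 50 genes planted at each size, 1 was called at 4-fold, 4 at 16-fold, 28 at 64-fold and 34 at 256-fold, all in the right direction. Of the unchanged genes 2 were called, the planted list was called and 0 of 24 unchanged lists were. Genes were simulated independently of each other, so this does not test lists whose members vary together. In the real gill comparison the estimated correlation was 0.5 for ribosomal proteins and 0.758 for mitochondrial transcripts. A gene not called here can therefore differ 16-fold or more. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used, and everything ran without network access on the deposited tables.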

Results

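Adult zebrafish carried a tamoxifen-dependent Cre recombinase driven by sox17, a transcription factor gene of endoderm. They also carried an mpeg1 cassette in which Cre swaps the red protein DsRedx for GFP. GFP therefore marks mpeg1-expressing cells with a sox17-expressing ancestor, called metaphocytes in the series description, and DsRedx marks the remaining mpeg1-expressing cells, called macrophages there. Cells of each color were sorted from gill and from intestine, 30 to 50 per sample. Their RNA was amplified as full-length cDNA by SMART-seq2 and sequenced as 150-base read pairs. Each of the 4 groups had n = 3 libraries, and all 12 libraries entered the analysis. The questions were how GFP cells differ from DsRedx cells of the same tissue, whether gill and intestine share that difference, and how the tissues differ within each color. Whether the replicates came from different fish is not given in the sources used here, so the p-values of single genes below measure the spread between these samples. P-values of camera and of Fisher's test compare genes with other genes and do not measure that spread. Levels are means in CPM (counts on the per-library scale of edgeR, with TMM-adjusted library sizes) with their standard deviation over n = 3 libraries. Intervals and floors for near-absent genes cover counting error only, because the reads carried no molecular barcodes.

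Replicates resembled each other only loosely. Libraries held from 5895669 to 12365233 counts. The number of genes with a count ran from 9506 to 10224 in gill DsRedx, 9931 to 11881 in gill GFP, 11312 to 11767 in intestine DsRedx and 12802 to 13278 in intestine GFP libraries. Pearson correlations of log2 CPM between replicates were 0.49 to 0.52 in gill DsRedx and 0.60 to 0.66 in gill GFP. They were 0.57 to 0.64 in intestine DsRedx and 0.72 to 0.78 in intestine GFP. Genes with a mitochondrial genome symbol held 0.689 to 4.09% of the counts, and the unnamed gene ENSDARG00000080337 alone held 5.31 to 17.4%. Genes without a symbol were not counted in the mitochondrial share, which can therefore be larger. Principal component 1 (23.9% of the variance) separated GFP from DsRedx libraries and component 2 (18%) separated the tissues. Component 3 (10.3%) set gill DsRedx 2 (191.6) apart from gill DsRedx 3 (-100.4). The common biological coefficient of variation over the 10666 genes tested was 1.42.

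The reporter genes themselves were partly visible. MPEG1 (ENSDARG00000055290, 1 of 3 genes sharing that symbol) encodes a perforin-like protein, and the mpeg1 promoter drives the cassette. It was read at 351 ± 107 CPM in gill GFP and 264 ± 42.9 CPM in intestine GFP cells, against 1538 ± 1054 CPM in gill DsRedx and 1815 ± 378 CPM in intestine DsRedx cells. SOX17 did not pass the filter on low counts. It had 1 count in the gill GFP libraries, 1, 47 and 552 counts in intestine GFP 1, 2 and 3, at most 3 counts in any intestine DsRedx library and 0 in gill DsRedx. The annotation held no entry for GFP, DsRedx or Cre.

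**Figure D1:**
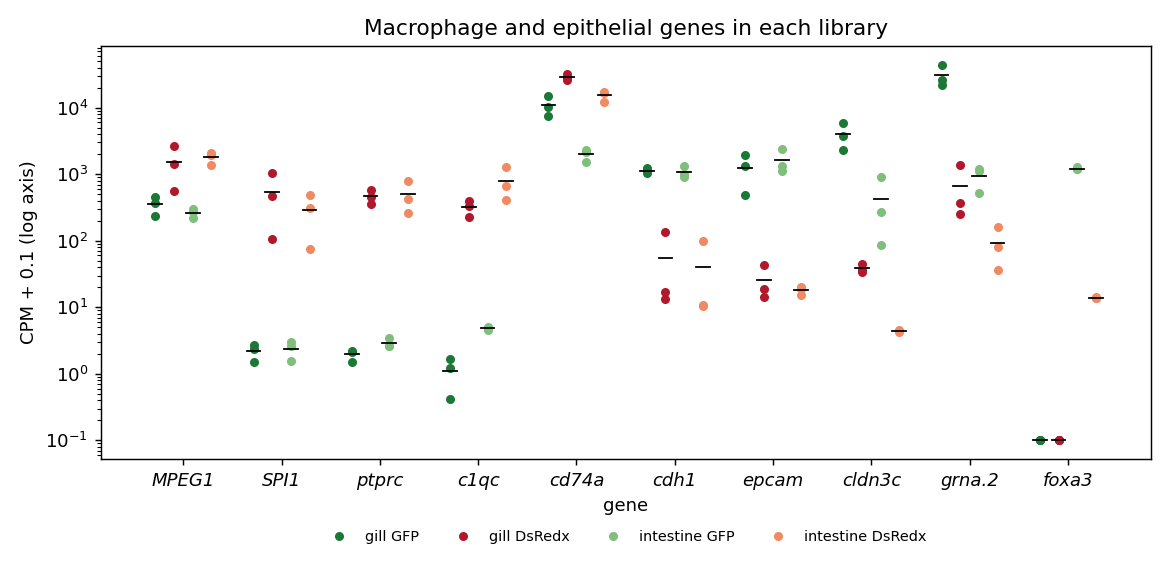
CPM of 10 genes in each of the 12 libraries, with the group mean as a bar. Gill GFP and gill DsRedx cells held ptprc at 1.85 and 464 CPM and cldn3c at 3994 and 38.2 CPM.

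In the gill, 13 of 23 tested leukocyte and macrophage identity genes were lower in GFP than in DsRedx cells and 10 were not called, among them spi1a at 175% and LCP1 at 97.7% of the DsRedx level. The pan-leukocyte phosphatase gene ptprc (CD45, ENSDARG00000071437) was 248-fold lower in GFP cells, at 1.85 ± 0.386 against 464 ± 118 CPM (log2 fold change -7.95, SE 0.94). Its adjusted p was 3.77e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg, which gave the adjusted p of every gene below. SPI1 (ENSDARG00000000767), encoding the myeloid master regulator PU.1, was 258-fold lower (2.1 ± 0.628 against 545 ± 477 CPM, adjusted p = 0.0003). The complement gene c1qc fell 318-fold (adjusted p = 3.77e-05) and the scavenger receptor gene marco 201-fold (adjusted p = 0.000726). In the opposite direction GFP cells carried the epithelial claudin cldn3c (cldnh, ENSDARG00000069503) at 3994 ± 1784 against 38.2 ± 5.32 CPM, 104.5-fold higher (adjusted p = 3.77e-05). That DsRedx level was 0.85 to 1.11% of the GFP mean, a low level shared by libraries of a tissue and described under the DsRedx comparison. The fold may be a reading of that level.

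Other adhesion genes rose with it. The epithelial cell adhesion gene epcam was at 1244 ± 724 against 25.4 ± 15.8 CPM (48.9-fold, adjusted p = 9.6e-05). E-cadherin, cdh1, was at 1134 ± 100.4 against 55.8 ± 70.4 CPM (20.3-fold, adjusted p = 0.0142). The progranulin paralog grna.2 (grn2), of a family of secreted growth factors, was at 30690 ± 11910 CPM in GFP cells, 46.5-fold above DsRedx cells (adjusted p = 3.77e-05). The S100 family gene icn (ictacalcin) rose 15.5-fold (2077 ± 993 against 134 CPM, adjusted p = 0.000336) and the clathrin adaptor AP2S1 97.8-fold (adjusted p = 0.00581). The trypsin inhibitor spink4 was read at 57.2 ± 48.9 CPM against 3 counts in all gill DsRedx libraries, a 348-fold ratio (95% counting interval 119 to 1690, adjusted p = 0.000804).

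Further named genes were lower in gill GFP cells. Heme oxygenase HMOX1 was 208-fold lower (14.4 ± 3.23 against 2987 ± 2073 CPM, adjusted p = 3.77e-05). The fatty-acid binding gene FABP7 (ENSDARG00000034650, 1 of 2 genes of that symbol) was 266-fold lower (adjusted p = 9.6e-05). The cholesterol exporter ABCA1 fell 248-fold (adjusted p = 0.00268) and the sterol carrier NPC2 (ENSDARG00000096979, 1 of 2) 149-fold (adjusted p = 0.00382). Among transcription factor genes, PRDM1 fell 269-fold (0.516 against 140.2 ± 62.8 CPM, adjusted p = 6.03e-05) and RUNX3 23.4-fold (85.0 against 1992 ± 594 CPM, adjusted p = 0.00122). ID2 fell 56.4-fold (adjusted p = 0.00195), FOSB 17.6-fold (adjusted p = 0.00247) and FOSL1 33.2-fold (adjusted p = 0.00687). Carbonic anhydrase ca2 fell 548-fold (0.153 against 96.3 ± 116 CPM, adjusted p = 0.00711), and havcr1, a TIM family phosphatidylserine receptor gene, 141-fold (adjusted p = 0.00251). The chemokine genes cxcl19 and cxcl8a fell 250.2-fold (4.37 ± 1.48 against 1097 ± 337 CPM, adjusted p = 6.52e-06) and 152-fold (adjusted p = 0.000814).

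Of the MHC class II genes 2 of 15 were lower in gill GFP cells. The MHC class II invariant chain gene cd74a was read at 10930 ± 3765 CPM in GFP and 29040 ± 2990 CPM in DsRedx cells, 2.66-fold lower in GFP (adjusted p = 0.00749, but 0.0758 by DESeq2). mhc2dab was 4.07-fold lower (adjusted p = 0.0251) and called in 9 of 12 fits that each left out 1 library. MPEG1 (ENSDARG00000055290) was 4.39-fold lower (adjusted p = 0.0376), a call kept in 5 of 12 such fits with a highest adjusted p of 0.17. Its paralog ENSDARG00000043093 fell 235-fold (adjusted p = 0.0388) with 5 of 12 fits and a highest adjusted p of 0.141. IRF8, a macrophage fate gene, was 32.7-fold lower (adjusted p = 0.034) and called in 7 of 12. The CSF1 receptor gene csf1ra had 0 counts in gill GFP cells against 4.33 ± 6.23 CPM, at least 33.1-fold lower by a floor of 3 counts over the group (adjusted p = 0.0435). It was called in 2 of 12 fits, with a highest adjusted p of 0.133. The T helper and macrophage marker cd4-1 was not called (adjusted p = 0.107, 76.8-fold on 2 counts, 95% counting interval 21.3 to 634), and csf1rb did not pass the filter on low counts.

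Over the whole gill comparison 490 of 10666 genes passed, 244 higher and 246 lower in GFP cells. Of 23 tested leukocyte and macrophage identity genes 13 were lower and 0 higher (0 and 15 when adjusted over the list alone). The list was lower at camera adjusted p = 3.32e-11, and at adjusted p = 0.0181 with an estimated correlation. Of 34 tight junction and epithelial adhesion genes 13 were higher and 0 lower (23 and 0 over the list alone). That list was higher at camera adjusted p = 2.53e-12, and at 0.00751 with an estimated correlation. Cytokines and chemokines were lower, with 1 member higher and 6 lower of 29 (2 and 13 over the list alone), at camera adjusted p = 5.95e-05 and 0.0146 with an estimated correlation.

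Further gill lists were lower by camera without holding when the correlation was estimated. These were phagocytosis machinery (0 higher and 6 lower of 24, adjusted p = 5.88e-05, 0.0937 with an estimated correlation) and lysosome and cathepsins (1 and 7 of 46, 5.95e-05, 0.0791 estimated). Lipid handling genes of macrophages had 4 lower of 16 (0.00268, 0.159 estimated), B cell markers 1 lower of 6 (0.00515, 0.0782) and immediate early and heat shock genes 5 lower of 45 (5.95e-05, 0.267). Dendritic cell genes had 1 higher and 3 lower of 12 (0.0163, 0.0937 estimated), and neutrophil and granulocyte markers 1 and 1 of 10 (0.045, 0.242). Interferon-stimulated genes had 1 lower of 27 (0.0282, 0.144 estimated). No member passed among 74 cytosolic ribosomal protein genes (median log2 fold change -1.34, camera adjusted p = 2.53e-12, 0.243 estimated) or 18 vacuolar ATPase subunits (0.014, 0.241). The same held for 24 cell cycle genes (0.00692, 0.283 estimated) and 13 mitochondrial transcripts (0.00765, 0.41). Epithelial transcription factors had 0 of 20 members called while the list was higher (0.0341, 0.109 estimated).

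Camera made no call in gill for MHC class II genes (2 of 15 lower, adjusted p = 0.107, median log2 fold change -1.03, mean 0.148) or pattern recognition receptors (3 of 14 lower, 0.107). Keratins had 2 of 12 higher (adjusted p = 0.962, median -0.428, mean 0.491, test downward). Endocytosis of soluble cargo (2 of 36 higher, 0.32), iron handling (1 of 13 lower, 0.191) and ionocyte and gill epithelium markers (0.185) were not called. T and NK cell markers (0.421) and enterocyte and goblet cell markers (0.72, median 0, mean 0.683, test downward) were not called either.

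The number of genes with a count differed between groups, so as a covariate it can also take out part of a group difference, here and below. With this covariate 244 genes passed in gill (140 higher, 104 lower). Not called then were mhc2dab (adjusted p = 0.129), MPEG1 (ENSDARG00000055290, 0.147, and ENSDARG00000043093, 0.129), IRF8 (0.0547), ABCA1 (0.0539), NPC2 (ENSDARG00000096979, 0.0875), ca2 (0.0571), cd74a and csf1ra.

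The gill calls depended on which libraries were in the fit: of 65 named genes called 26 were called in all 12 fits with 1 library left out. Leaving out gill GFP 1, 2 or 3 gave 256, 231 and 233 genes in place of 490, leaving out gill DsRedx 3 gave 307 (105 higher, 202 lower), and leaving out intestine GFP 1, 2 or 3 gave 303, 284 and 295. Leaving out gill DsRedx 1 or 2 also tilted the balance, to 142 higher and 249 lower and to 153 and 230.0. The 16 lists called became 10 without gill GFP 1 or gill GFP 3. Removing a low level shared by all libraries of a tissue, described under the DsRedx comparison, left 197 genes (124 higher, 73 lower). Calls ended although log2 fold changes grew for epcam (5.61 to 7.45, adjusted p = 0.0762), grna.2 (5.54 to 6.89, 0.135), cdh1 (4.35 to 5.24, 0.23), ID2 (-5.82 to -5.92, 0.141) and cxcl8a (-7.24 to -8.34, 0.062). They ended with little change in RUNX3 (-4.55 to -4.33, 0.132), FOSL1 (-5.05 to -4.86, 0.168) and MPEG1 (ENSDARG00000055290, -2.13 to -1.84, 0.131). Because the removal lowers low counts most, it favors larger folds by itself.

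In the intestine, 13 of 23 leukocyte and macrophage identity genes were lower in GFP cells and 10 were not called, among them spi1a at 149% and LCP1 at 63.4% of the DsRedx level. ptprc was 177-fold lower than in DsRedx cells (2.79 ± 0.502 against 497 ± 273 CPM, log2 fold change -7.47, SE 0.92, adjusted p = 4.38e-05). SPI1 was 128-fold lower (2.27 ± 0.743 against 292 CPM, adjusted p = 0.000612) and IRF8 249-fold (adjusted p = 0.00337). GFP cells held epcam at 1619 ± 703 against 18 ± 2.69 CPM (adjusted p = 3.82e-05) and cldn3c at 417 ± 428 against 4.29 ± 0.0905 CPM (97.1-fold, adjusted p = 4.22e-05). cdh1 was at 1080 ± 229 against 40.0 ± 51.2 CPM (27.0-fold, adjusted p = 0.00772).

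Genes of gut epithelium were also higher in the intestine GFP libraries. The gut endoderm transcription factor gene foxa3 was at 1215 ± 51.7 against 13.8 ± 0.385 CPM (88.1-fold, adjusted p = 0.000256) and cdx1b rose 104-fold (adjusted p = 0.00598), called in 9 of 12 left-out fits with a highest adjusted p of 0.0874. The microvillus gene VIL1 (villin) was at 913 ± 227 against 9.36 ± 0.521 CPM (97.3-fold, adjusted p = 0.0006). The ileal bile-acid binding gene FABP6 was at 793 ± 193 against 7.52 ± 0.344 CPM (105-fold, adjusted p = 0.000612). The keratin krt4 rose 85.4-fold (1529 ± 143 against 17.9 ± 1.65 CPM, adjusted p = 0.00727) and icn reached 3141 ± 212 against 44.7 ± 15.2 CPM (adjusted p = 1.03e-05). The DsRedx levels of foxa3, cdx1b, VIL1, FABP6 and krt4 lay near 1% of their GFP means, at the low shared level described under the DsRedx comparison. Their folds may be readings of that level. The phosphoinositide kinase gene pip5k1ba rose 131-fold (adjusted p = 0.000335) and the magnesium transporter NIPAL4 127-fold (adjusted p = 0.000522). With the low shared level removed, log2 fold changes rose steeply for epcam (6.49 to 16.9), cldn3c (6.60 to 14.94), pip5k1ba (7.03 to 12.58) and NIPAL4 (6.99 to 11.92). The folds of these 4 genes may be readings of that level as well. grna.2 was 10.3-fold higher, at 949 against 92.7 ± 63.3 CPM (adjusted p = 0.00187), and its reporter difference did not differ by test from that in gill (difference of log2 fold changes 2.18, adjusted p = 0.22).

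MHC class II presentation was lower in intestine GFP cells. cd74a was 7.61-fold lower (2003 ± 412 against 15250 ± 2611 CPM, log2 fold change -2.93, SE 0.31, adjusted p = 1.03e-05) and mhc2dab 7.23-fold (adjusted p = 0.00224). The antigen-processing proteases ctss2.1 and LGMN were 27.9-fold (66.0 ± 8.17 against 1839 ± 466 CPM, adjusted p = 0.000126) and 14.6-fold lower (adjusted p = 0.000255). MPEG1 (ENSDARG00000055290) was 6.89-fold lower (adjusted p = 0.00759) and called in all 12 left-out fits, while ENSDARG00000043093 of the same symbol was not called (adjusted p = 0.174). csf1ra was 212-fold lower (adjusted p = 0.034) and called in 7 of 12 such fits, marco was 97.2-fold lower (adjusted p = 0.00155) and cd4-1 was not called (adjusted p = 0.0717).

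Further genes fell in intestine GFP cells. c1qc fell 165-fold (4.78 ± 0.238 against 790.5 ± 448 CPM, adjusted p = 6.12e-05), c1qb 128-fold (adjusted p = 0.00139) and havcr1 122.5-fold (adjusted p = 0.00242). FABP7 (ENSDARG00000034650) fell 171-fold (adjusted p = 0.000168), PRDM1 231-fold (adjusted p = 6.12e-05), RUNX3 30.7-fold (adjusted p = 0.000578) and cxcl8a 245-fold (adjusted p = 0.000409). The lysosomal receptor gene scarb2a was 150-fold lower (1.24 against 188 ± 101 CPM, adjusted p = 0.00211). The vacuolar ATPase subunit ATP6V0C (ENSDARG00000057853, 1 of 2) was 8.68-fold lower (adjusted p = 0.00505) and the Fc receptor chain fcer1gl 34.5-fold (adjusted p = 0.0006).

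The test called 439 genes in the intestine, 223 higher and 216 lower in GFP cells. Macrophage identity genes had 13 lower of 23 (17 over the list alone, camera adjusted p = 1.67e-16, 0.00281 with an estimated correlation). Tight junction genes had 17 higher of 34 (28 over the list alone, with 1 lower), at camera adjusted p = 1.23e-15 and 0.00267 estimated. MHC class II genes had 5 lower of 15 (9 over the list alone, with 1 higher), at camera adjusted p = 8.75e-06 and 0.0094 estimated. Epithelial transcription factors had 4 of 20 higher (16 over the list alone, 9.99e-08, 0.00281 estimated) and keratins 5 of 12 (8.75e-06, 0.0211 estimated). Enterocyte and goblet cell markers had 3 of 15 higher and 12 not called (median log2 fold change 5.78, 6.6e-05, 0.0358 estimated). The absorptive markers FABP2, FABP1, apoa1a and RBP2, picked by hand from these 15, overlapped between the groups. They summed to 29.3, 1070 and 97.5 CPM in intestine GFP and to 181, 499 and 17.5 CPM in intestine DsRedx libraries. Lower lists that held with an estimated correlation also included phagocytosis machinery (6 of 24, 1.4e-08, 0.0193) and cytokines and chemokines (7 of 29 with 1 higher, 2.88e-06, 0.00315). Lysosome and cathepsins had 7 of 46 lower and 2 higher (1.64e-06, 0.0215 estimated), B cell markers 1 of 6 lower (0.000514, 0.02) and T and NK cell markers 1 of 10 lower (0.00604, 0.0371).

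Lists that lost the call with an estimated correlation were all lower in intestine GFP cells. They were vacuolar ATPase (1 of 18 lower, camera adjusted p = 6.6e-05, 0.0582 estimated), lipid handling (3 of 16, 0.000544, 0.0692) and cell cycle (0 of 24, 6.6e-05, 0.156). Neutrophil markers had 1 higher and 1 lower of 10 (0.0165, 0.177 estimated), immediate early and heat shock genes 3 lower of 45 (0.00169, 0.364) and ribosomal proteins 0 of 74 (median log2 fold change -0.672, 1.47e-06, 0.357). Camera gave no call for pattern recognition receptors (adjusted p = 0.133), dendritic cell genes (0.126), endocytosis (0.388), interferon-stimulated genes (0.207) or mitochondrial transcripts (0.265). Iron handling (0.421, median -0.0107, mean 0.342) and ionocyte markers (0.72, median 0, mean 0.377, test downward) were not called either.

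Here too the number of calls moved with single libraries. Leaving out intestine GFP 1, 2 or 3 gave 181, 191 and 182 genes and leaving out intestine DsRedx 1, 2 or 3 gave 265 (86 higher, 179 lower), 253 (95, 158) and 270 (88, 182) in place of 439. With detected genes as a covariate 132 genes passed (51 higher, 81 lower), and foxa3, FABP6, VIL1 (adjusted p = 0.291), cdx1b (0.471), krt4 (0.146), mhc2dab (0.128), MPEG1 (ENSDARG00000055290, 0.207), csf1ra (0.859), c1qb (0.0629), havcr1 (0.0957) and ATP6V0C (0.116) were not called. The number of detected genes did not overlap between these groups (12802 to 13278 in intestine GFP, 11312 to 11767 in intestine DsRedx libraries), so that fit does not separate it from color. Of 71 named genes called 31 stayed called in all 12 fits with 1 library left out. Removing the low shared level gave 270 genes (180 higher, 90 lower). It ended the calls of grna.2 (log2 fold change 3.36 to 3.86, adjusted p = 0.291), cdh1 (4.75 to 5.56, 0.246), RUNX3 (-4.94 to -4.91, 0.0931) and fcer1gl (-5.11 to -5.25, 0.0725), whose folds stayed about as large or grew, which the removal favors by itself.

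**Figure D2:**
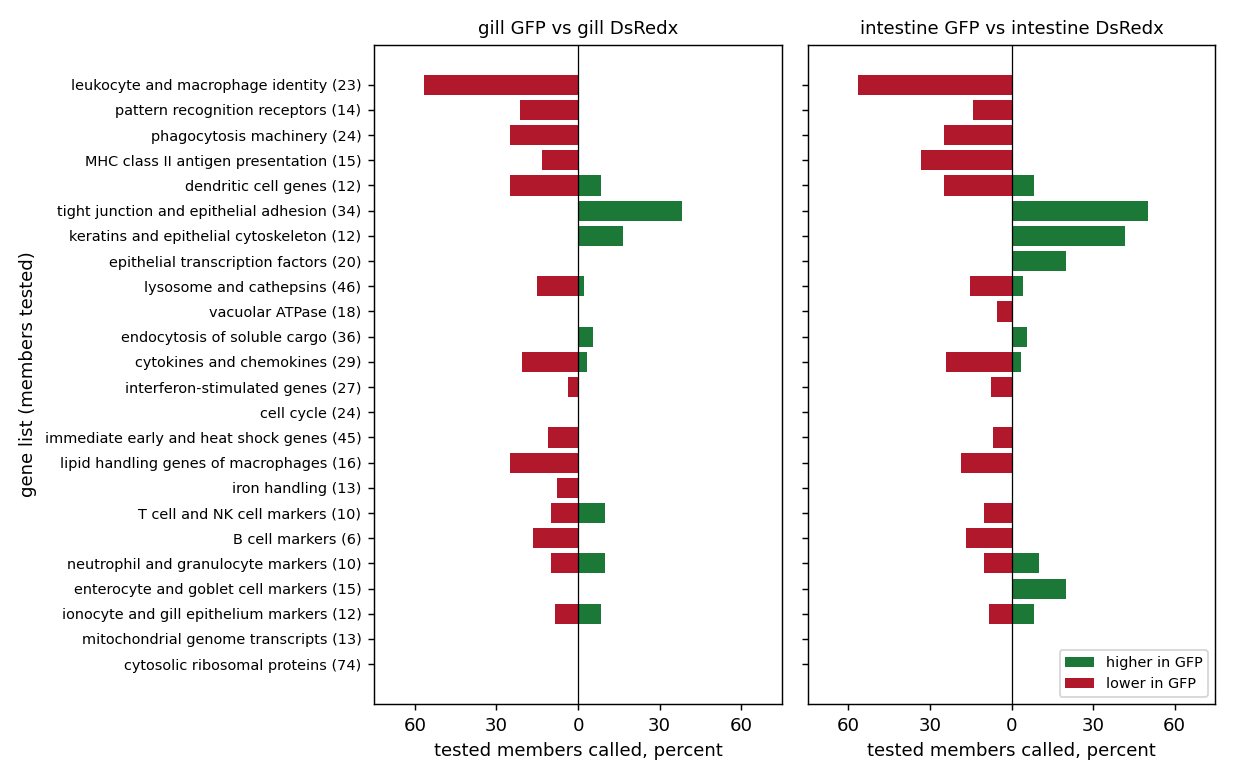
Percent of each list's tested members called higher or lower in GFP cells, in gill and in intestine. Tight junction genes had 13 of 34 higher in gill and 17 of 34 in intestine, macrophage identity genes 13 of 23 lower in each tissue.

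Gill and intestine shared much of the GFP difference. The genes higher in both numbered 117 where 5.1 would be shared if the calls were unrelated (Fisher p = 7.15e-142), and 127 were lower in both against 4.98 (p = 6.61e-164). ptprc, SPI1, c1qc, marco, PRDM1 and FABP7 (ENSDARG00000034650) lay in the lower set, and cldn3c, epcam, cdh1, grna.2 and icn in the higher one. Only sb:cb1058 passed with opposite signs, and its gill DsRedx level, 111 ± 191 CPM, had a standard deviation above its mean. The tissues had no library in common, but both contrasts came from 1 fit with shared dispersions and filter. A gene with little spread is favored in both, so the Fisher p-values do not measure independent calls. The log2 fold changes correlated at r = 0.73 over the 684 genes called in at least 1 tissue and at r = 0.35 over all 10666. Leaving out gill GFP 1, 2 or 3 gave 157, 141 and 158 shared genes in place of 244. Leaving out intestine GFP 1, 2 or 3 gave 105, 110 and 114, and intestine DsRedx 1 or 2 gave 151 and 148. The overlap of calls between gill and intestine was 105 with the low shared level removed, 81 with detected genes as a covariate, 135 with only the 2 groups compared in each fit and 919 by DESeq2. The numbers expected of unrelated calls were not worked out for these.

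**Figure D3:**
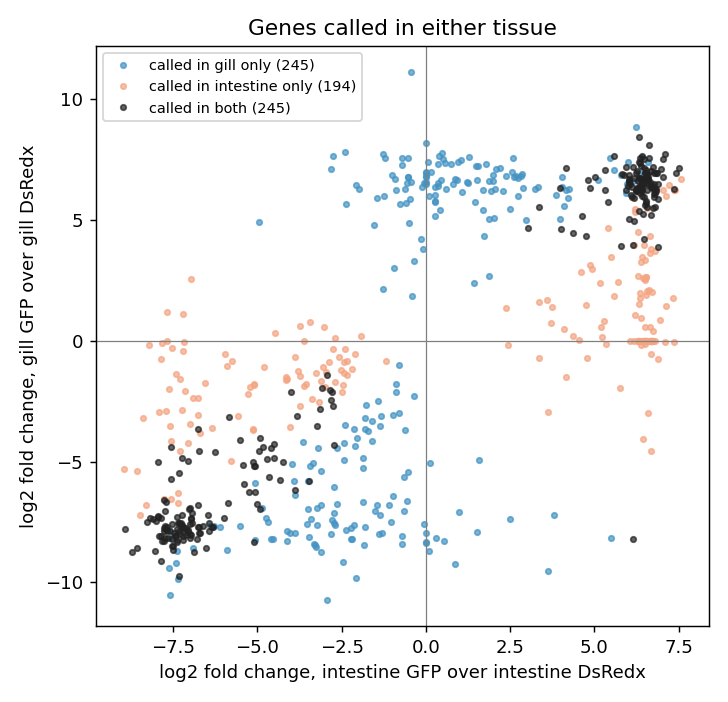
Log2 fold change of GFP over DsRedx cells in gill against intestine for 684 called genes. 245 passed in both tissues, 245 in gill only and 194 in intestine only.

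Averaged over the tissues the reporter difference reached 1904 genes, 1125 higher and 779 lower in GFP cells, a balance that turned in some fits. With no filter 724 were higher and 913 lower, and with 1 DsRedx library left out the lower genes outnumbered the higher ones each time (587 and 764, 590.0 and 790.0, 520.0 and 734 higher and lower without gill DsRedx 1, 2 and 3, and 441 and 712, 495 and 643, 488 and 695 without intestine DsRedx 1, 2 and 3). Macrophage identity genes were lower in 16 of 23 members (camera adjusted p = 4.07e-16, 0.00581 with an estimated correlation) and phagocytosis genes in 11 of 24 (6.08e-08, 0.0276). MHC class II genes were lower in 8 of 15 with 1 higher (0.000428, 0.0276 estimated), and tight junction genes higher in 25 of 34 (9.13e-14, 0.00428). Lysosomal genes had 3 higher and 18 lower of 46 (3.01e-07, 0.0276 estimated) and cytokines 2 and 14 of 29 (7.03e-07, 0.00428). Of 24 cell cycle genes 6 were lower and 0 higher (camera adjusted p = 8.83e-05, 0.167 with an estimated correlation). Leaving out gill GFP 1 or 2 gave 1157 and 1243 genes, gill DsRedx 3 gave 1254, intestine GFP 1, 2 or 3 gave 961, 964 and 902, and intestine DsRedx 1, 2 or 3 gave 1153, 1138 and 1183. Removing the low shared level gave 1220 genes and the replicate block 1157. Detected genes as a covariate gave 335 (193 higher, 142 lower). Limma on log2(TPM + 1) gave 1404 higher and 454 lower.

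GFP libraries of the tissues differed in genes of gut epithelium. Intestine GFP libraries held the tetraspanin-like gene TM4SF4 at 8321 ± 995 CPM against 0 counts in gill GFP cells, at least 63600-fold by the 3-count floor (adjusted p = 7.67e-10). The intestinal claudin cldn15lb was at 2588 ± 546 CPM against 0 (at least 19800-fold, adjusted p = 1.08e-07). The gut regulators foxa3 (at least 9290-fold, adjusted p = 2.08e-06), cdx1b (at least 2750-fold, adjusted p = 0.000256) and GATA6 (at least 1350-fold, adjusted p = 0.00365) also had no count in gill GFP cells. The same was true of VIL1 (at least 6980-fold, adjusted p = 5.96e-06) and FABP6 (at least 6060-fold, adjusted p = 1.03e-05).

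Gill GFP cells instead held regulators with 0 counts in intestine GFP cells. pou2f3, a transcription factor gene of chemosensory tuft cells, was at 176 ± 104 CPM (at least 2090-fold, adjusted p = 0.00356). PAX1 (ENSDARG00000073814, 1 of 2), a pharyngeal pouch gene, was at 151 ± 65.7 CPM (at least 1790-fold, adjusted p = 0.00508) and GATA3 at 150.2 ± 97.0 CPM (at least 1780-fold, adjusted p = 0.00508). The interleukin-17 receptor family gene il17rel was at 146 ± 31.3 CPM (at least 1730-fold, adjusted p = 0.00561). cd74a was 5.45-fold higher in gill than in intestine GFP cells (log2 fold change 2.45, SE 0.30, adjusted p = 7.8e-05) and grna.2 32.3-fold (adjusted p = 0.000107). The chemokine receptor gene CXCR4 (ENSDARG00000041959, 1 of 2) was 13.4-fold higher (6374 ± 2721 against 476 ± 301 CPM, adjusted p = 0.00102).

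The comparison of GFP cells called 217 genes, 75 higher and 142 lower in gill. MHC class II genes were higher in gill GFP cells (3 of 15, 7 over the list alone, camera adjusted p = 0.000129, 0.0402 with an estimated correlation). Enterocyte markers were lower (5 of 15, 9.84e-12, 0.0381 estimated), as were keratins (4 of 12 with 1 higher, 2.19e-05, 0.0445) and epithelial transcription factors (6 of 20 with 1 higher, 0.00269, 0.0402). T and NK cell markers (2 higher of 10, camera adjusted p = 0.0172, 0.0843 with an estimated correlation) and neutrophil markers (1 higher of 10, 0.0101, 0.195) lost the call with an estimated correlation. Shared features were not called: SPI1 (log2 fold change -0.12, adjusted p = 0.985), epcam (-0.38, 0.905), cdh1 (0.07, 0.992) and MPEG1 (ENSDARG00000055290, 0.41, 0.87). None of 23 macrophage identity genes passed (camera adjusted p = 0.396). Leaving out gill GFP 1, 2 or 3 gave 139, 96 and 103 genes and leaving out intestine GFP 1, 2 or 3 gave 120, 97 and 100. Removing the low shared level gave 47 genes. It ended the calls of pou2f3 (adjusted p = 0.106), PAX1 (0.126), GATA3 (0.116), il17rel (0.126) and GATA6 (0.088), whose folds are floors, and of grna.2 (log2 fold change 5.02 to 4.83, adjusted p = 0.328). With detected genes as a covariate 18 genes passed (9 higher, 9 lower), and cdx1b (adjusted p = 0.261), GATA6 (0.56), pou2f3 (0.11), PAX1 (0.12), GATA3 (0.12), il17rel (0.11), cd74a (0.443), grna.2 (0.199) and CXCR4 were not called.

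Between DsRedx cells of gill and intestine edgeR called 81 genes, 24 higher and 57 lower in gill, and both the number and the balance moved with the method. DESeq2 called 1639 (625 higher, 1014 lower) and edgeR with no filter 267 (133 higher, 134 lower). Without gill DsRedx 1 there were 26 higher and 26 lower, and without gill DsRedx 3 there were 29 and 26. MPEG1 (ENSDARG00000055290, log2 fold change -0.24, adjusted p = 0.871), SPI1 (0.90, adjusted p = 0.621), IRF8 (-0.06, adjusted p = 0.989) and marco (-0.46, adjusted p = 0.846) were not called. Of 23 macrophage identity genes 0 were called, although csf1ra was at 4.33 ± 6.23 CPM in gill DsRedx and 184.2 ± 80.55 CPM in intestine DsRedx cells. The lipid transporter ABCB4 was read at 271 ± 156 CPM in intestine DsRedx against 0 counts in gill DsRedx cells (at least 1650-fold, adjusted p = 0.0166). The retinol carrier RBP2 (ENSDARG00000070038, 1 of 2) was at 198 ± 224 CPM against 0 (at least 1200-fold, adjusted p = 0.0285), called in 7 of 12 left-out fits with a highest adjusted p of 0.0834. Gill DsRedx cells held the chemokine ccl20a.3 at 447 ± 233 against 5.62 CPM (79.3-fold, adjusted p = 0.0226), called in 11 of 12 left-out fits. The water channel AQP1 (ENSDARG00000023713, 1 of 2) was at 172 CPM against 0 (at least 1310-fold, adjusted p = 0.0166), called in 10 of 12. spp1, siglec15l and chl1a, with standard deviations above their gill DsRedx means of 296, 276 and 263 CPM, had highest adjusted p of 0.234, 0.224 and 0.214 on leaving out a library.

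Many of these genes were those of gut epithelium at a low and even level. TM4SF4 was read at 92.0 ± 5.6 CPM in intestine DsRedx libraries and at 0 in gill DsRedx (at least 559-fold, adjusted p = 1.18e-07). cldn15lb was at 27.3 ± 1.95 CPM (at least 166-fold, adjusted p = 3.24e-05), foxa3 at 13.8 ± 0.385 CPM (at least 83.7-fold, adjusted p = 0.000612) and FABP6 at 7.52 ± 0.344 CPM (at least 45.7-fold, adjusted p = 0.00384). Enterocyte markers were the only list called (4 of 15 lower in gill, camera adjusted p = 8.07e-06, 0.307 with an estimated correlation). In 26 of the 81 genes the higher group lay at this level, near 1% of the GFP cells of its own tissue. With the level removed 6 genes passed by edgeR and 0 of 23 named genes kept the call. TM4SF4 and foxa3 then had a log2 fold change of 0. Also not called then were ABCB4 (adjusted p = 0.281), RBP2 (0.284) and AQP1 (0.247), whose folds are floors, and ccl20a.3 (log2 fold change 6.31 to 6.18, adjusted p = 0.22). Leaving out gill DsRedx 1 or 2 gave 52 and 38 genes, intestine GFP 1, 2 or 3 gave 49, 43 and 35, and intestine DsRedx 1, 2 or 3 gave 53, 37 and 49. RLE scaling gave 49 (21 higher, 28 lower). Detected genes as a covariate left 3 genes, with ABCB4 (adjusted p = 0.362), RBP2 (0.749), AQP1 (0.283), ccl20a.3 (0.324), cldn15lb (0.279), foxa3 (0.33) and FABP6 (0.362) not called.

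The low level also entered the reporter differences. Of 244 genes higher in gill GFP cells 167 had such a level in the DsRedx group, and of 246 lower ones 139 had it in the GFP group. The corresponding numbers were 175 of 223 and 88 of 216 in the intestine. For those of them with counts in the lower group, ptprc at 0.4% of the DsRedx level in gill GFP cells among them, the fold may be a reading of the low level. Whether the cells' own low expression gave it was not tested for them.

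**Figure D4:**
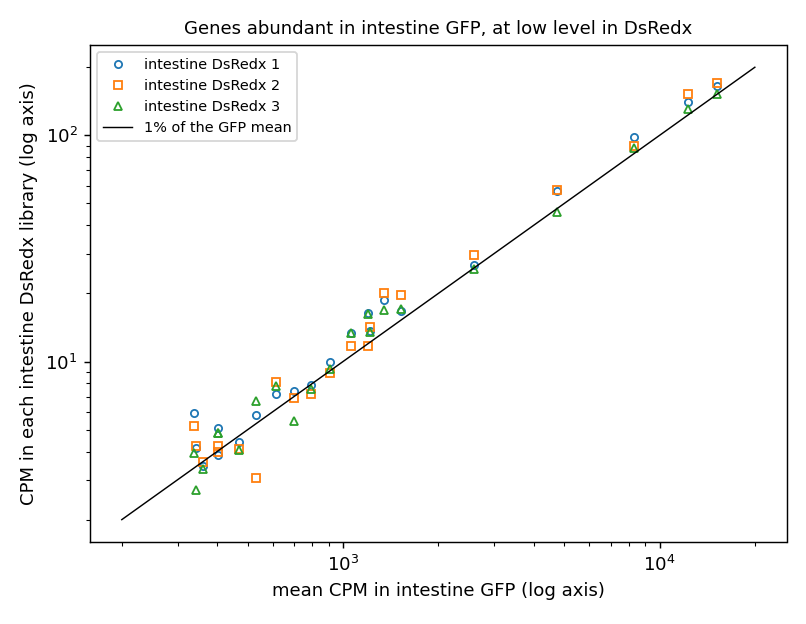
CPM of 21 genes in each intestine DsRedx library against their mean in intestine GFP cells, with a line at 1%. TM4SF4 lay at 92.0 against 8321 CPM and cdx1b at 3.46 against 360.1 CPM.

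The GFP to DsRedx difference itself changed between tissues for 16 genes, the signed difference of log2 fold changes, gill minus intestine, being positive for 6 and negative for 10. The unnamed gene si:dkey-56m19.5 was at 2.47 CPM in gill GFP cells and at 477, 419.9 and 432 CPM in gill DsRedx, intestine GFP and intestine DsRedx cells (difference of log2 fold changes -7.55, adjusted p = 0.0084). HMOX1 had a log2 fold change of -7.70 in gill and of -1.81 in intestine (difference -5.89, adjusted p = 0.0348). CXCR4 (ENSDARG00000041959) was low only in intestine GFP cells (476 against 6374, 3688 and 5098 CPM, difference 4.21, adjusted p = 0.0348). The palmitoyltransferase ZDHHC18 was too (1.03 against 186 to 216 CPM, 7.68, adjusted p = 0.0445), while the water channel AQP3 was low only in intestine DsRedx cells (0.800 against 83.0 to 397 CPM, -7.24, adjusted p = 0.0348). MHC class II genes (median difference 1.46, camera adjusted p = 0.0101, 0.167 with an estimated correlation) and keratins (-2.23, 0.000661, 0.167) differed as lists. None of the 12 named genes kept its call in all left-out fits. Leaving out gill GFP 1, 2 or 3 gave 4, 2 and 1 genes, intestine GFP 1, 2 or 3 gave 5, 1 and 3, and intestine DsRedx 1 or 2 gave 8 and 3. The balance of signs was not fixed: upper-quartile scaling gave 4 positive and 11 negative, while the filter of 10 CPM in 3 libraries, and likewise leaving out intestine DsRedx 3, gave 9 positive and 6 negative. DESeq2 called 834 (430.0 positive, 404 negative) and edgeR with no filter 107 (48 positive, 59 negative). Detected genes as a covariate left 2 genes, and HMOX1 (adjusted p = 0.064), CXCR4 (0.064), ZDHHC18 (0.181) and AQP3 (0.103) were not called.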

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

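All tests of an explanation in this part, the removal of the low shared level and the counts over other splits of the samples were chosen after the results were seen, while the test of the difference between tissues was planned. The 16 genes and 2 lists here stood out because the GFP to DsRedx difference itself differed between gill and intestine by edgeR's quasi-likelihood test with Benjamini-Hochberg or, for lists, by camera.

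Values below are gill minus intestine differences of log2 fold changes, with the adjusted p and the adjusted p once the low shared level was removed. The difference was negative for sb:cb1058 (-14.35; 0.0348; 0.0888), ace, angiotensin-converting enzyme (-13.66; 0.0348; 0.194), ptprh (-11.03; 0.0445; 0.148), si:dkeyp-73b11.8 (-10.51; 0.0445; 0.0191), si:dkey-56m19.5 (-7.55; 0.0084; 0.000782), AQP3 (-7.24; 0.0348; 0.0154), shtn2 (-6.60; 0.0348; 0.00458), HMOX1 (-5.89; 0.0348; 0.000786), pleca (-5.09; 0.0445; 0.289) and ANXA4 (-4.46; 0.0445; 0.244). It was positive for CXCR4 (ENSDARG00000041959; 4.21, 0.0348, 0.0473), marcksl1a (4.91, 0.0445, 0.244), MYH9 (6.29, 0.0348, 0.244), degs1 (6.35, 0.0445, 0.245), ZDHHC18 (7.68, 0.0445, 0.0191) and PRKCB (9.49, 0.0348, 0.0719). Where a call ended with the level removed the difference had not shrunk, with MYH9 at 7.38, marcksl1a at 5.38, degs1 at 6.83, pleca at -6.03 and ANXA4 at -5.61. The removal lowers low counts most and so favors larger differences by itself, and these sizes are no support for the calls. In gill DsRedx cells sb:cb1058 (111 ± 191 CPM) and ace (53.3 ± 92.1 CPM) had standard deviations above their means. The value of si:dkeyp-73b11.8 is the model's own for a gene with no count in gill GFP cells, so its size is not fixed by the data. MHC class II genes had a camera adjusted p of 0.0101 (fry 0.0528) and keratins of 0.000661 (fry 0.0528), and neither list was called with an estimated correlation (0.167 each) or by fry. Over splits of the samples 12 of 100 gave at least as many as these 16 genes, the highest other one, 1904, being the split that exchanges the colors in 1 tissue. A split that mixes or exchanges colors in 1 tissue turns the reporter difference into a tissue difference (up to 194 genes among the remaining 98), so these splits give no level for chance and do not bear on the 16.

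The low, even level of 26 genes called between the DsRedx groups, 21 higher in intestine and 5 in gill, was weighed against 3 explanations. Own low expression in DsRedx cells could not be excluded. The median coefficient of variation over the 3 libraries was 0.102, against 1.51 for genes of like CPM and 0.79 for the other called genes. But the 26 genes were picked by being called and by lying at or under the 0.5% limit in all 3 libraries. Both steps favor an even level, so the small spread does not decide the question. For carry-over of reads or free RNA between libraries of a tissue, genes with at least 3000 counts in the other libraries of a tissue were looked at (1676 to 2292 per library). They were at 0 in 1 case, against 860 cases for genes with as many counts in the other tissue (2058 or 2563 per library). The first set also holds genes abundant in replicates of the library's own group, which expression alone keeps above 0. The counts therefore allow carry-over but do not separate it from expression. A whole GFP cell sorted into DsRedx libraries cannot be told apart, because the highest library median, 1.12% of the GFP level (lowest 1.06%, 21 genes), lies below the 2% of 1 cell in 50 but a cell poor in RNA could give it. With the level removed TM4SF4, foxa3 and FABP6 were at 0 in both DsRedx groups (log2 fold change 0, adjusted p = 1 each), so their calls ended because nothing was left to compare, and whether carry-over arose in the sorted suspension, the amplification or the sequencing stays open.

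MPEG1 (ENSDARG00000055290) in GFP cells was weighed against an admixture of macrophages. In every gill GFP library it was at 15.5% or more of the DsRedx mean while the median of 12 other macrophage genes lower in GFP reached at most 0.635%, and in intestine GFP libraries it was at 11.9% or more against at most 0.91%. Cells with the mean DsRedx profile bring all transcripts alike, so their admixture is excluded as the source of MPEG1 in both tissues. The 12 genes were picked for being lower in GFP. Of them 8 were under 1% in each tissue, while CEBPB stood at 11.3% in gill. DsRedx cells were not shown to be uniform, so a subset rich in MPEG1 and poor in these genes was not excluded. Transcription of MPEG1 by GFP cells themselves, which the reporter design needs, stays open as a hypothesis found and examined on the same data, and reads shared with the other genes of that symbol were not tested.

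The gut genes VIL1 and FABP6 in intestine GFP cells were weighed against an admixture of absorptive enterocytes. Their sum over that of FABP2, FABP1, apoa1a and RBP2 ranged 44.1-fold over the 3 intestine GFP libraries (ratios 1.26 to 55.6), VIL1 and FABP6 themselves varying 1.59-fold and the other genes 36.5-fold. Without intestine GFP 2 the range was 2.53-fold, so 1 library carried most of it and enterocyte admixture cannot be told apart from expression by the GFP cells, the rule for this test having been changed after its values were seen. The genes of this ratio were picked by hand from the 15 tested enterocyte and goblet cell markers, whose median log2 fold change was 5.78 in intestine. Enterocyte-like types without FABP2 and expression in the lineage itself could both give such values.

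Other splits of the samples were counted for each number of called genes. With 3 against 3 libraries there are only 10 splits, too few to judge, and the real one gave the most in each comparison: 236 genes in gill (highest other 8), 1079 in intestine (highest other 0), 289 between GFP groups (0) and 54 between DsRedx groups (2), that is 1 of 10 each time. For the mean reporter effect 1 of 100 splits, the real one, reached 1904 genes and the highest other gave 163.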

How the results depend on the processing

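The alternative settings were chosen before the data were examined except 2, the removal of the low shared level and the fit without the most abundant gene, which were chosen after the results were seen. For the causes of the changes below, the cause was not tested unless named. Called genes moved beyond 1.5 times as follows, in the order gill, intestine, GFP tissues, DsRedx tissues, mean, difference, overlap (490, 439, 217, 81, 1904, 16 and 244). Detected genes as a covariate gave 244, 132, 18, 3, 335, 2 and 81, and ended 153 named gene calls. The 236 named results compared also held genes not called in the main fit. Detected genes differed between groups, so this covariate can also take out part of a group difference. Removal of the low level gave 197, 270, 47, 6 and 1220 for the first 5 and 105 for the overlap. Only the 2 groups compared gave 236 in gill, 1079 in intestine and 135 shared, with fewer samples in the fit. DESeq2 gave 2618, 1876, 1092 and 1639, 834 for the difference and 919 for the overlap of calls between gill and intestine. Limma on log2(TPM + 1) gave 755 (568 higher, 187 lower), 1155 (883, 272), 761 and, for the difference, 269. With a pseudocount of 0.1 it gave 772, 1158, 790.0, 151 and, for the difference, 0 (limma-trend, 1266 genes at unadjusted p under 0.05, where edgeR called 16 and DESeq2 834). With no filter it gave 918, 583 and 89 for intestine, GFP tissues and the difference. With no filter on counts 267 genes passed in DsRedx tissues and 107 for the difference. RLE gave 49 and 9 there, and 177 higher and 268 lower in gill. The replicate block gave 1157 for the mean. Lists called fell with an estimated correlation from 16 to 3 in gill, 17 to 11 in intestine, 17 to 7 for the mean, 1 to 0 in DsRedx tissues and 2 to 0 for the difference (fry also 0). The 1 list of DsRedx tissues became 3 with RLE, 4 with the strict filter, 2 with the level removed and 3 with fry.

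Leaving out 1 library at a time gave 231 to 492 genes in gill, 181 to 543 in intestine, 96 to 273 between GFP groups, 35 to 83 between DsRedx groups, 902 to 1380 for the mean, 1 to 17 for the difference and 105 to 234 shared. Lists ran from 10 to 18 in gill, 16 to 18 in intestine, 6 to 7, 1 to 3, 15 to 18 and 2 to 4 in the same order. Named genes stayed called or stayed uncalled in 5111 comparisons with an alternative, lost the call in 1188 and gained it in 13. They turned in 2: VIL1 (2.73, adjusted p = 0.389) and krt4 (3.23, adjusted p = 0.488) between DsRedx groups with the low level removed. List results stayed in 957, lost the call in 105 and turned in 0. RLE shifted the median log2 fold change of all genes by -0.203 in intestine, 0.253 between GFP groups, 0.258 between DsRedx groups and -0.225 for the mean. Upper-quartile scaling shifted it by 0.185 in intestine, 0.114 between DsRedx groups, 0.107 for the mean and -0.18 for the difference, so changes of that size have no fixed sign. The 59 called list results all kept their call and direction under RLE. The number block gave 347, 385, 218, 75 and 23 genes and 187 shared. Libraries of the same number but different group correlated at -0.044 to 0.046 after group means were removed (18 pairs), those of different number at -0.0438 to 0.0494 (36 pairs), and 5 of 12 matched best with their own number, so no pairing was visible. SOX17, sox32 and csf1rb did not pass the filter on low counts, SOX17 with 552 counts in 1 library, and whether depth limited any result was not tested.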

Other observations

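The readings of SPIC, il22ra2 and library gill DsRedx 2 in this part were chosen only after the results were seen, and no explanation was tested. GFP cells did not lack every leukocyte gene. The PU.1 relative spi1a stood at 175% of the DsRedx level in gill (1646 against 943 CPM) and 149% in intestine, the actin bundler LCP1 at 97.7 and 63.4%, CORO1A at 248 and 182% and the GTPase rac2 at 90.8 and 116%. None of them was called by edgeR's quasi-likelihood test with Benjamini-Hochberg (spi1a adjusted p = 0.268 in gill and 0.56 in intestine). In the same cells SPI1, ptprc and CMKLR1 stood at 0.384, 0.4 and 0.449% in gill and at 0.777, 0.562 and 0.682% in intestine. DsRedx cells held both PU.1 paralogs, spi1a at 943 and SPI1 at 545 CPM in gill, so only SPI1 differed by test, and reads shared between the paralogs were not checked. SPIC, an ETS family relative of PU.1 picked after its values were seen, was higher in GFP cells, at 908 ± 314 against 60.7 ± 90.9 CPM in gill (log2 fold change 3.90, adjusted p = 0.0248) and 651 ± 156 against 5.50 ± 0.644 CPM in intestine (6.88, adjusted p = 0.000674). The soluble interleukin-22 receptor gene il22ra2, also picked afterwards, was 6.70 log2 units higher in intestine GFP cells (893 ± 78.1 against 8.57 CPM, adjusted p = 0.00527) and not called in gill (2.01, adjusted p = 0.2125).

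Library gill DsRedx 2 held more of a few genes than the other gill DsRedx libraries did, with il22ra2 at 891 CPM against 12.43 and 7.59, SPIC at 166 against 8.60 and 7.87, cdh1 at 137 against 13.4 and 16.8, epcam at 43.5 against 14.2 and 18.6 and grna.2 at 1354 against 370.2 and 255 CPM in gill DsRedx 1 and 3. Of these SPIC, cdh1, epcam and grna.2 were called higher in gill GFP cells and il22ra2 was not. Its correlations with gill DsRedx 1 and 3 over all genes (0.4855 and 0.5027) lay near the 0.5196 between those. Principal component 3 nevertheless set it apart, at 191.6 against -55.58 and -100.4 for gill DsRedx 1 and 3. It also had the lowest number of genes with a count, 9506.

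The endodermal factor sox32 was read only in gill GFP libraries, at 0, 22 and 1 counts, and did not pass the filter on low counts.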
